A study of Arabidopsis thaliana with 16 samples.

How the data were processed

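RNA of Arabidopsis thaliana was measured on expression arrays in 16 samples of 1 channel each, 8 labelled WT and 8 labelled gun1, each numbered 1 to 8. WT is the ecotype Columbia 0, and gun1 is the gun1-1 mutant, which the labels describe as defective in plastid signaling. The tissue, growth conditions, dyes, scanner settings, normalization and build are not given in the sources used here. Groups were taken from the sample titles. The labels do not say that the numbered samples came from separate plants, so p-values measure only the spread between these samples, which may be technical.

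The deposited values are intensities on a linear scale, one for each of 3439 probes and 16 samples. Nothing in the labels states how they were made. In the table every sample runs from exactly 0 to exactly 100, 2 probes lie at 100 in all 16 samples, and no value is negative. The top of 100 could come from scaling each sample to its brightest spots or from a cap, and the zeros from a cut at 0. The background correction and the scale before any such step stay unknown, and a level of 1 means 1% of the highest value of a sample. The medians of the deposited columns ranged from 0.130 to 0.157 in WT and from 0.216 to 0.259 in gun1, so no common median had been set. The number of arrays limits the precision.

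Because the medians differed by more than 0.1 on the log2 scale, the samples were quantile normalized with limma 3.58.1 in R 4.3.3. Values deposited as 0, and all values below the 5th percentile of the remaining positive values, were set to that floor of 0.0313, and log2 was taken. The difference gun1 minus WT was tested for each probe with limma's lmFit and eBayes, 8 samples against 8, with no covariate, two-sided, and adjusted by the Benjamini-Hochberg method at a threshold of 0.05. All adjusted p-values printed for single genes are from limma. Left out of the test were 20 probes with 1 constant value in all 16 samples after this step, 18 at the floor and 2 at 100, an exclusion that the design written beforehand did not name. That left 3419 probes, and a probe past the threshold is referred to as called. A fold is 2 to the power of the log2 difference, so it compares geometric means, while levels are arithmetic means ± SD of the normalized intensity over 8 samples. A fold of a gene with samples at the floor depends on the floor.

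Probes were named through the platform's annotation table. It lists 1 gene for 692 probes, several genes for 870 and none for 1877, and genes were named only from the 692. Of these, 690 were matched by Entrez gene number to the RefSeq gene table of assembly TAIR10.1, which supplied current symbols and locus names and nothing else, and 2 kept the platform's symbol. Unnamed probes were tested but are not reported singly here.

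Before the data were examined, the design, the alternatives, 15 gene lists of 285 loci, 13 lists by name or locus pattern and the rule for genes to name were fixed. The rule takes the 12 largest rises and the 12 largest falls among called probes with 1 gene, 8 genes around GUN1 and plastid signaling wherever measured, and up to 4 members of each list. Another 8 lists were put together from the names of the measured genes after the annotation and a few raw bright values, but no test result, had been seen. Genes of those added lists, and list members beyond 4, were picked after their values were seen. Lists with 5 or more measured members were tested with limma's camera at a preset correlation of 0.01, two-sided, with an estimated correlation and with fry as alternatives. The alternatives covered the scaling, the filter on dim probes, the floor, the replicate number as a block, the treatment of consecutive numbers, the variance model, an exact rank sum test and leaving out each sample. Array medians and numbers of zeros were compared by exact permutation of all splits into 8 and 8. Figures were drawn with matplotlib 3.10.9.

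The numbers pair the samples across genotypes. Deviations from the group mean were correlated between WT and gun1 samples of the same number in all 8 cases, with r across probes from 0.143 to 0.421 and a mean of 0.239, against a mean of -0.0338 for different numbers. Each sample of either group correlated best with its own number in the other group, 8 of 8 in both directions. The pairing comes from these values, since the labels give only the numbers.

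The procedure was tested on simulated data with the spread of the 3419 probes of the comparison of gun1 with WT. It recovered 37 of 100 probes changed 1.5-fold and 63 of 100 changed 2-fold, and 9 of its 109 calls were unchanged probes. In that run the samples were independent, and none of the changed probes was drawn from the dimmest in WT. Recovery of the dimmest probes, or with correlated consecutive numbers, was therefore not measured. With no change at all but the correlation of consecutive numbers found in the data, 0.365, the procedure made 3 calls among 3419 probes. At an unadjusted p under 0.05 there were 324. The part shared by consecutive numbers was drawn separately for each probe, and samples of the same number were not correlated across genotypes. False calls from differences that many probes share were therefore not measured.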

Results

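Expression profiles of the gun1-1 mutant and of wild type (WT), both in the ecotype Columbia 0, were compared on arrays of 3439 probes, with 8 samples per genotype. GUN1 is a plastid-localized pentatricopeptide repeat protein of the pathway by which plastids signal their state to the nucleus. The comparison asks which transcripts differ between mutant and wild type. The targeted gene could not be used to check the labels, because neither GUN1 (AT2G31400) nor HY1, HY2, GUN4, CHLH, HEMA1, LHCB1.2 or RBCS1A has a probe naming that gene alone. The deposited values run from 0 to 100 in every sample; how they were made is not stated.

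Samples of one genotype resembled each other more than those of the other. The mean correlation of a sample with its own group, across probes, was 0.887 ± 0.00806 in WT and 0.888 ± 0.00747 in gun1 (SD, n = 8 each), and with the other group it was 0.821 ± 0.00912 for WT samples. The first principal component carried 29.3% of the variance and placed all 8 gun1 samples above every WT sample. The second carried 13.5% and set the numbers 7 and 8 of both genotypes apart from the others. Deposited medians were higher in gun1, at 0.238 ± 0.0186 against 0.143 ± 0.0113 in WT, and zeros were fewer, at 227 ± 29.4 against 349 ± 78.8 per sample (SD, n = 8 each). The exact permutation p, two-sided, was 0.000155 for the medians, the smallest that 8 against 8 can give, and 0.000622 for the zeros. Consecutive numbers of a genotype had similar medians, so these p-values, which count 8 separate samples per genotype, may be too small.

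Transcripts differed widely between the genotypes. The clearest rise was that of AT4G35660, from 0.804 ± 0.227 in WT to 7.51 ± 1.099 in gun1 (SD, n = 8 each), or 9.65-fold (log2 3.27, SE 0.18, adjusted p = 7.16e-09). AT3G18870, of the mTERF family of organelle gene regulators, rose 7.05-fold (log2 2.82, SE 0.22, adjusted p = 8.46e-08), and AT2G46050, a pentatricopeptide repeat protein, rose 5.05-fold (log2 2.34, SE 0.30) with 2 WT samples at the floor of 0.0313, to which lower values were set. AT4G16410 fell from 2.12 ± 0.227 to 0.472 ± 0.0953, and was 4.54-fold higher in WT (log2 -2.18, SE 0.14, adjusted p = 2.48e-08). AT5G58330, a plastid NADP-dependent malate dehydrogenase, fell from 2.24 ± 0.139 to 0.689 ± 0.206, a level 3.43-fold higher in WT (log2 -1.78, SE 0.21, adjusted p = 1.12e-05). Each of these 5 genes moved the same way in all 8 numbers. The size of these changes depended on the scaling: with a common median the log2 difference was 2.52 for AT4G35660, -2.84 for AT4G16410 and -2.49 for AT5G58330, and unscaled it was 3.49 for AT3G18870 and 3.09 for AT2G46050.

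In all, limma called 1088 of 3419 probes (31.8%), 567 higher and 521 lower in gun1. Of these, 552 differed by 2-fold or more, 318 higher and 234 lower, and 720 had the same direction in all 8 numbers. Among the 689 tested probes that name 1 gene, 249 were called, 124 higher and 125 lower. Consecutive numbers of one genotype deviated together on average, and averaging them into 4 samples against 4 reduced the calls to 592, or to 782 with the replicate number as a block as well, an alternative chosen after seeing the data. With consecutive numbers as a random block and all 16 samples kept, 733 were called. The split by direction followed the scaling: 34.2% of calls were higher in gun1 with a common median, 85.5% with the deposited values unscaled and 52.1% here, where the median log2 difference over all probes was -0.18, 0.41 and -0.05.

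**Figure D1:**
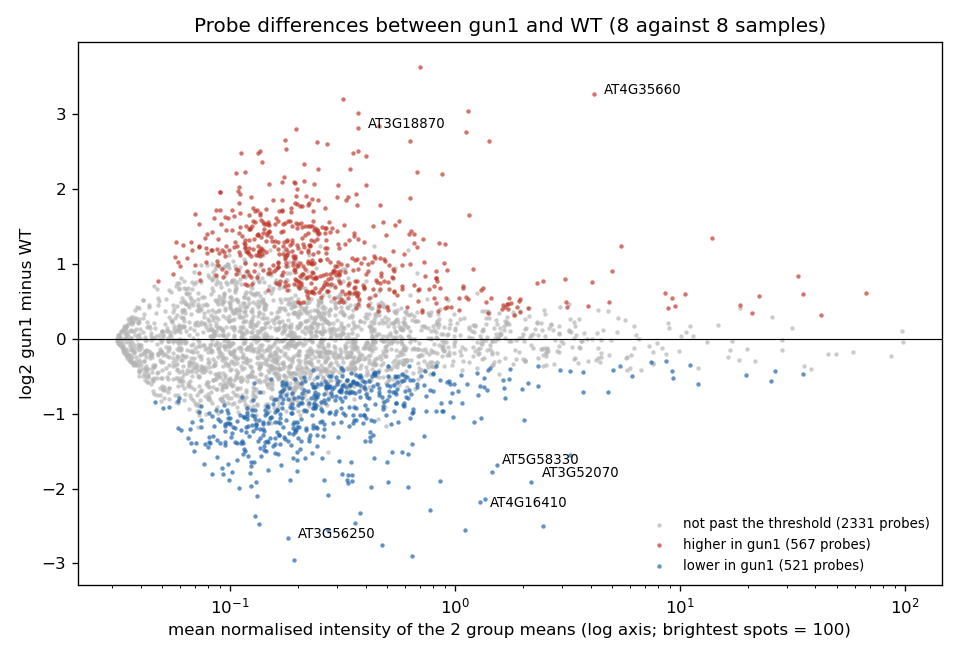
Difference gun1 minus WT on the log2 scale (y axis) against the mean of both groups' normalised intensities (log x axis) for the 3419 tested probes, with the 567 called higher in red, the 521 called lower in blue and the others in grey. AT4G35660 stands out among the brighter probes that rose and AT4G16410, AT3G52070 and AT5G58330 among the brighter ones that fell.

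Among the 12 largest rises, AT3G11150, with 2 WT samples at the floor, rose 6.30-fold and AT2G36480, with 1, rose 6.27-fold, the latter from 0.198 ± 0.0894 to 1.06 ± 0.0746 (SD, n = 8 each). AT1G22700 (PYG7), an assembly factor of photosystem I, rose 4.67-fold (log2 2.22, SE 0.28, adjusted p = 2.25e-05), with 6 of 8 WT samples at the floor. APTX, an aprataxin-like gene of DNA repair, rose 4.65-fold with 7 of 8 WT samples at the floor. AT2G32040, of the folate-biopterin transporter family, rose 4.31-fold (log2 2.11, SE 0.40) with 2 WT samples at the floor, but the call was lost in the numbers 5 to 8 alone (adjusted p = 0.148). AT4G16490 rose 3.99-fold and AT2G37000 (TCP11), a TCP transcription factor gene, 3.91-fold, with 1 and 6 WT samples at the floor. The fold of a gene with samples at the floor depends on it: with the floor at the 20th and at the 1st percentile, the log2 difference was 0.97 and 3.36 for AT1G22700, 0.89 and 3.89 for APTX, 0.63 and 3.25 for AT2G37000 and 1.71 and 3.13 for AT3G11150. For AT2G36480, AT2G46050, AT2G32040, AT4G16490 and AT2G48090, with 1 or 2 such samples, it lay between 1.22 (AT2G48090) and 2.46 (AT2G36480) with the former and between 2.09 and 2.89 with the latter. AT1G73740 and AT2G48090 both rose 3.62-fold, and AT2G48090, with 1 WT sample at the floor, lost its call in the numbers 5 to 8 alone (adjusted p = 0.229).

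Among the 12 largest falls, AT3G56250 was 6.29-fold and AT1G62780 5.14-fold higher in WT, each with 3 gun1 samples at the floor; with the floor at the 20th and at the 1st percentile, the log2 difference was -1.65 and -3.23 for AT3G56250 and -1.21 and -2.74 for AT1G62780. FBL17, an F-box gene of cell cycle control, fell from 0.210 ± 0.0512 to 0.0536 ± 0.0286 (SD, n = 8 each), with 4 gun1 samples at the floor (log2 -2.10, SE 0.28, adjusted p = 3.24e-05; -1.14 and -2.71 with those floors). AT3G52070 fell from 3.45 ± 0.521 to 0.918 ± 0.162 (log2 -1.91, SE 0.14, adjusted p = 6.63e-08; -2.68 with a common median). AT4G33760, a class II aminoacyl-tRNA synthetase, was 3.74-fold and AT3G53580, a diaminopimelate epimerase of lysine synthesis, 3.42-fold higher in WT, the latter with 5 gun1 samples at the floor (log2 -0.69 and -2.73 with those floors). AT1G76450, of the PsbP family of photosystem II, was 3.92-fold higher in WT (log2 -1.97, SE 0.34; -0.98 and -2.46 with those floors) with 3 gun1 samples at the floor, a call lost without scaling (adjusted p = 0.0601) and in the numbers 1 to 4 alone (0.0596). AT2G01400, AT2G11270 and AT2G39000 were 3.51-fold, 3.39-fold and 3.19-fold higher in WT, with 5, 3 and 3 gun1 samples at the floor (log2 -0.61 and -2.17 for AT2G01400, -1.19 and -2.48 for AT2G11270 and -0.67 and -1.91 for AT2G39000 with those floors), the latter 2 not called without scaling (adjusted p = 0.0756 and 0.113). AT2G11270 was also not called in the numbers 1 to 4 (0.0697) or 5 to 8 (0.112) alone.

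**Figure D2:**
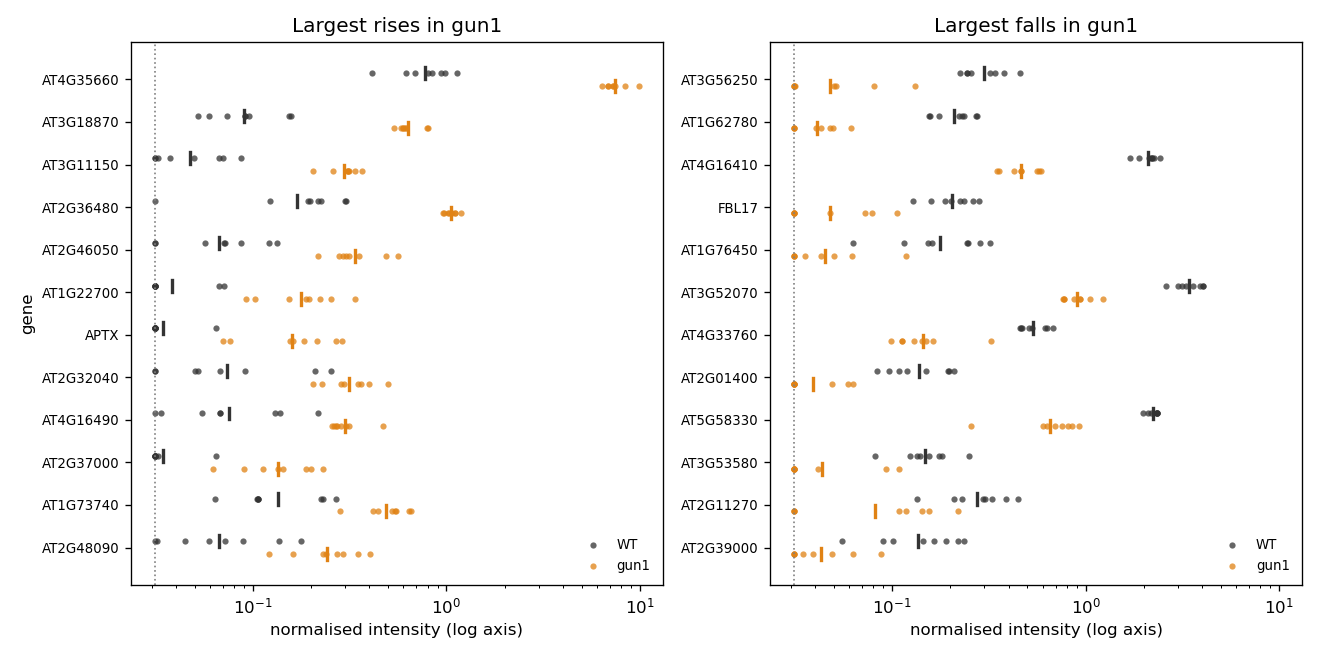
Normalised intensity (log x axis) of the 12 genes with the largest rises (left) and the 12 with the largest falls (right) in each of the 8 WT (grey) and 8 gun1 (orange) samples. Bars mark geometric means and the dotted line the floor of 0.0313; AT4G35660 lies between 0.414 and 1.14 in WT and between 6.38 and 9.84 in gun1.

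Among the lists fixed beforehand, plastid ribosomal proteins were the one with enough measured members for a test, 6 of 37. Of these, 3 fell, 0 rose and 3 were not called: AT3G13120 had a log2 difference of -0.70 (SE 0.18, adjusted p = 0.00724, lower in 8 of 8 numbers), AT1G64510 of -0.61 (SE 0.19, adjusted p = 0.0232) and AT4G01310 of -0.50 (SE 0.17, adjusted p = 0.0325). Adjusted over the list alone, 3 were called as well. The median of the list was -0.45, and 0.02 without scaling, where the median of all probes was 0.41. Camera did not call the list (p = 0.170, and p = 0.371 with an estimated correlation), while fry, which asks whether the genes move one way on balance, gave p = 0.0301. None of the 3 was called with consecutive numbers averaged (adjusted p = 0.0838, 0.137 and 0.180). AT1G64510 and AT4G01310 also lost their calls without scaling (adjusted p = 0.892 and 0.414) and under cyclic loess (0.0530 and 0.0585), and AT4G01310 when WT replicate 1, 2 or 6 or gun1 replicate 3, 4 or 8 was left out (adjusted p from 0.0548 to 0.0612).

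Photosynthesis genes of the photosystem, Calvin cycle and tetrapyrrole lists mostly stayed short of the threshold. SBPASE, a Calvin cycle phosphatase, fell (log2 -0.51, SE 0.15, adjusted p = 0.0138, lower in 8 of 8 numbers), but was not called without scaling (adjusted p = 0.483) or with consecutive numbers averaged (0.123). PSBW, a subunit of photosystem II, rose from 37.7 ± 4.37 to 46.9 ± 3.86 (SD, n = 8 each; log2 0.32, adjusted p = 0.0371), yet had an adjusted p of 0.0646 with the replicate number as a block, 0.261 with consecutive numbers averaged and a log2 of -0.25 with a common median. Its call was also lost when WT replicate 3, 4, 5, 6 or 7 or gun1 replicate 3, 4 or 8 was left out (adjusted p from 0.0509 to 0.0672). PSAN (log2 0.18), PSBY (-0.18, though lower in 8 of 8 numbers), the light-harvesting gene LHB1B2 (-0.02), PRK (-0.03), CHLM (-0.60, adjusted p = 0.0518) and AT1G74470 (0.09), a geranylgeranyl reductase of chlorophyll synthesis, were not called. Adjusted over the list alone, 1 of 3 photosystem II genes, 1 of 2 Calvin cycle genes, 1 of 2 tetrapyrrole genes and 0 of 1 photosystem I genes were called. An adjustment over so few genes is slight. With a common median, 7 of these 8 genes were called lower in gun1 and 0 higher, so their calls depend on the scaling. The direction also turned with the scaling for all but PSBY and SBPASE, which stayed lower.

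Of the remaining lists with a measured gene, AT3G52960, a plastid peroxiredoxin and the 1 measured gene of the antioxidant list, rose from 0.288 ± 0.0895 to 0.571 ± 0.138 (SD, n = 8 each; log2 1.02, SE 0.22, adjusted p = 0.00208, higher in 8 of 8 numbers), a call lost in the numbers 5 to 8 alone (adjusted p = 0.0556). FATB, the 1 measured gene of fatty acid synthesis, had a log2 difference of -0.76 (adjusted p = 0.0549). Adjusting over a list of 1 gene changes nothing, so it passed there only by limma's unadjusted p of 0.0184. FATB also passed in 11 of 33 alternatives, among them the replicate number as a block (adjusted p = 0.0309). The thioredoxin reductase NTRC (-0.17), the chaperonins Cpn60beta3 (-0.85, adjusted p = 0.0697) and Cpn60beta4 (-0.53), CCS (-0.45) and the proteases TPP2 (-0.24) and SPPA (0.33) were not called. The plastid ribosomal genes AT3G54210 (0.02), AT5G65220 (0.35) and AT1G29070 (-0.39) were not called either. Another 18 lists matched 0 measured genes, among them the seed and senescence markers, so material of another tissue or state was not tested here. The name patterns read only symbols and synonyms. They missed measured genes such as AT2G46050, a pentatricopeptide repeat protein, so an empty list by name does not mean that none was measured.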

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

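The ranking of the pairings of numbers, the tests of the random block against the count and of a scale factor with an added amount, and averaging with a replicate block were chosen after the result was seen; the other tests of this part were set beforehand. With a test for a sample far from the rest of its group of 8, 13 of 124 groups (10.5%) stood out. The test flags about 1 in 20 groups by chance only where values are independent and normal. Gene levels entered it as linear intensities, some tied at the floor, so an excess over chance is not shown. In 5 cases most of the other samples lay at the floor of 0.0313: APTX in WT replicate 2 (0.0645), AT2G37000 in WT replicate 8 (0.0643), AT5G65220 in WT replicate 6 (0.0930) and in gun1 replicate 5 (0.191), and SPPA in WT replicate 1 (0.175). Samples high against the median of the others were gun1 replicate 1 for AT4G16490 (0.473 against 0.273), gun1 replicate 2 for AT1G76450 (0.118 against 0.0355), gun1 replicate 5 for AT4G33760 (0.323 against 0.130), WT replicate 5 for AT3G13120 (0.877 against 0.693) and gun1 replicate 7 for NdhN (0.337 against 0.137). TPP2 was at the floor, 0.0313, in WT replicate 5 against 0.217 in the others. IYO, a regulator of RNA polymerase II, was high in replicate 6 of both genotypes, at 0.506 against 0.342 in WT and 0.416 against 0.115 in gun1. No explanation was tested for these single values.

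The count of 1088 called probes was weighed against chance, the consecutive numbers and the scaling. A chance assignment of single samples is argued against. Of 100 splits of the 16 samples into 8 and 8, 1 gave as many calls, the real one, and the highest other gave 4. Of 100 splits that exchanged WT and gun1 within numbers, 1 gave as many, again the real one. The highest other of these, with 1 number exchanged, gave 311. Both kinds of split exchange single samples, although consecutive numbers deviated together. They therefore cannot exclude chance differences between preparations that several samples may share. Median scaling, with 1551 calls, kept 84.7% of the 1088 in the same direction and turned 11, cyclic loess kept 88.9% and the unscaled values 68.1%, which argues against the scaling as the source of most of the count, though not of the direction of single genes or of the balance of directions. Counting consecutive numbers as separate replicates is argued against as the source of the whole count, since 733 calls, 67.4% and all among the 1088, were left with them as a random block. That share lay only just above a bound set after the result was seen. The calls lost stay open: averaging left 592, 54.4% of the count and between the bounds set beforehand, and averaging with a replicate block 782, with 719 of the 1088 kept. The genotype, and a difference in dye, slide or growth between the groups, which the labels do not give, stay open and could not be separated by this design.

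Deposited medians were 0.143 ± 0.0113 in WT and 0.238 ± 0.0186 in gun1. A single scale factor per array is argued against: the log2 ratio of gun1 to WT was higher in the classes 5 and 6 of 10 equal classes of probes, ordered by mean level, than in the brightest class, by 0.75 ± 0.05 (SD over 8 numbers). With a constant amount of signal added to every gun1 spot, the difference gun1 minus WT would be equal in all classes. It was larger in the classes 5 and 6 than in the class 2, by 0.0611 ± 0.00483 (SD over 8 numbers). Zeros were more frequent in WT, so a cut of the values at 0 could shrink the difference in the class 2. That comparison alone therefore cannot decide. A scale factor and an added amount together would make the difference change in one direction with level. The difference rose from 0.0398 ± 0.00614 in the class 2 to 0.118 ± 0.0105 in the class 6. In the class 9 it was 0.0364 ± 0.0343, lower than in the class 6 by 0.0816 ± 0.0319 (SD over 8 numbers). This fall argues against a constant amount alone. The rise from the class 2 may come from a cut at 0 and cannot decide about a scale factor with an added amount. In the brightest class the log2 ratio was -0.00235 ± 0.0504 (SD over 8 numbers), which puts a scale factor near 1. Such a factor would leave the difference nearly equal in the classes 6 and 9. The fall between these classes therefore argues against a scale factor with an added amount. A dye or detector response that differed between groups, and the genotype stay open as untested.

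Consecutive numbers within a genotype (1 and 2, 3 and 4, 5 and 6, 7 and 8) deviated together on average, with a mean r across probes of 0.198 against -0.198 for other numbers of a genotype, where centring on the group mean alone puts unrelated samples below 0; the r ranged from -0.00925, for 5 and 6 in WT, to 0.356. Of the 105 ways to pair 8 numbers, 1 reached so high a mean in each genotype, that of the consecutive numbers. A candidate explanation is 2 readings of one hybridisation or a shared day of consecutive numbers, which the labels neither state nor exclude. No biological explanation was tested for this pattern. The p-values over 8 samples may then be too small.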

How the results depend on the processing

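Averaging consecutive numbers with a replicate block, and leaving out the numbers 7 and 8, were chosen after seeing the data; the other alternatives were planned. The 1088 calls became 592 with consecutive numbers averaged, 583 in the numbers 1 to 4 alone and 324 in the numbers 5 to 8 alone, all with fewer samples; the other counts ran from 733 (consecutive numbers as a random block) to 1551 (common median), with 1425 unscaled, 1091 under cyclic loess, 1031 by the exact rank sum test, 853 without the numbers 7 and 8, 782 averaged with a replicate block and 996 to 1065 with 1 sample left out. With the replicate number as a block 1293 probes were called, and beyond PSBW and FATB it changed no other call of a named gene or list. Quantile normalization as an alternative is the setting used. Dim probes limit the precision: the median residual SD in log2 was 0.74 in the dimmest of 4 equal classes of probes and 0.29 in the brightest, and 43.2% of values in the dimmest lay at the floor.

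Of the 24 genes with the largest rises and falls, 19 were called in the same direction under every alternative that kept them and 0 turned. Of the other 34 genes followed, 16 were called, and each lost its call under 1 or more alternatives, 9 calls in all with consecutive numbers averaged. A common median lowers the unscaled log2 difference by the same amount for every gene with no sample at the floor. For AT4G35660 it went from 3.25 to 2.52 and for AT3G18870 from 3.49 to 2.76. A small difference can therefore turn by the choice of scaling alone, and no other cause was tested. Directions turned for the genes that follow. With a common median the log2 differences were PSAN -0.64, PSBW -0.25, AT1G74470 -0.72, AT3G54210 -0.66, CRR21 -0.0263 and HEMA3 -0.0455. Without scaling they were LHB1B2 0.0193, CHLM 0.0392, NTRC 0.44, Cpn60beta4 0.38, TPP2 0.46, AT1G29070 0.35, CCS 0.11, PIFI 6.42e-05, CRR41 0.0566 and OTP85 0.37. Under cyclic loess LHB1B2 had 0.0518 and PRK 0.0361; in the numbers 1 to 4 alone LHB1B2 had 0.0697, AT1G74470 -0.0498, AT3G54210 -0.0429 and CCS 0.0936; in the numbers 5 to 8 alone PRK had 0.14 and TPP2 0.0598. LHB1B2 had 0.0155 without the numbers 7 and 8, and SPPA -0.0178 with the floor at the 20th percentile. With 1 sample left out LHB1B2 ranged from -0.0714 to 0.0297, PRK from -0.0714 to 0.00873 and AT3G54210 from -0.0381 to 0.0819. Genes not called passed in some such fits: FATB without WT replicate 2 or gun1 replicate 4, 5 or 6 (adjusted p from 0.0265 to 0.0336), CHLM without WT replicate 4 or gun1 replicate 1, 3 or 7 (0.0326 to 0.0492) and Cpn60beta3 without gun1 replicate 4 (0.0330). Over all alternatives, FATB passed in the same direction in 11 of 33, CHLM in 8 of 33 and Cpn60beta3 in 3 of 32.

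The list of plastid ribosomal proteins, the 1 list fixed beforehand that was tested, was not called in any camera fit, but limma's fry, a test of another question, called it, 1 of the fixed lists (median log2 -0.45, adjusted p = 0.0301). Leaving out dim probes, the random block and the rank sum test gave no list value. The mean correlation of samples with their own group was 0.888 ± 0.00752 and became 0.913 over the 1710 brighter probes.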

Other observations

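The tests over chromosomes and beyond GUN1 in this part were chosen after the result was seen, and the genes named here, other than AT3G52960 and PSBW, were picked after their values were seen. Nuclear genes for the plastid NDH complex, which carries cyclic electron flow around photosystem I, and for chlororespiration were lower in gun1 in 4 of 6 measured cases, and 0 were higher. NdhS fell from 5.86 ± 0.597 to 3.75 ± 1.21 (SD, n = 8 each; log2 -0.71, SE 0.19, adjusted p = 0.00926, lower in 8 of 8 numbers). NdhN fell by 0.86 on the log2 scale (SE 0.28, adjusted p = 0.0263), PIFI by 0.88 (SE 0.25, adjusted p = 0.0128) and CRR41 by 0.50 (SE 0.16, adjusted p = 0.0227), although the unscaled values gave 6.42e-05 for PIFI and 0.06 for CRR41. CRR21 (0.14) and OTP85 (-0.47), editing factors of NDH transcripts, were not called. The list passed fry (adjusted p = 0.000318) but not camera (adjusted p = 0.243, and adjusted p = 0.348 with an estimated correlation), and its median of -0.61 became 0.03 unscaled, where the median of all probes was 0.41 and 1 gene was called higher and 1 lower; with a common median 0 were higher and 3 lower, and under cyclic loess 0 and 5. With consecutive numbers averaged NdhS, NdhN and CRR41 were not called (adjusted p = 0.0932, 0.130 and 0.132), nor were PIFI, NdhN and CRR41 with them as a random block (0.0722, 0.0559 and 0.0705), nor any of the 4 in the numbers 1 to 4 or 5 to 8 alone (0.0567 to 0.308); PIFI, with 1 gun1 sample at the floor, was not called with a common median (0.0800) or with the floor at the 1st percentile (0.0539), and NdhN was not called without gun1 replicate 6 (0.05005).

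Among 5 genes of pigment and siroheme synthesis, 2 rose and 0 fell. Z-ISO, an isomerase of carotenoid synthesis, rose from 0.0794 ± 0.0159 to 0.195 ± 0.0840 (SD, n = 8 each), or by 1.19 on the log2 scale (SE 0.25, adjusted p = 0.00213). HEMA3, of the glutamyl-tRNA reductase family that starts tetrapyrrole synthesis, rose by 0.68 on the log2 scale (SE 0.13, adjusted p = 0.000825), though it had -0.05 with a common median. The locus number of HEMA3, AT2G31250, is close to that of GUN1, AT2G31400. The chromosome segment considered below is therefore not excluded for HEMA3. With a common median 1 gene of this list was called higher and 2 lower (median -0.05), and unscaled 3 higher and 0 lower. Among 5 cell wall enzymes 2 glycosyl hydrolase genes rose, GH9B11 by 1.32 (SE 0.26, adjusted p = 0.00104) and GH9B16 by 1.72 (SE 0.33, adjusted p = 0.00106), with 1 and 6 of 8 WT samples at the floor and, for GH9B16, 1 gun1 sample, and 3 were not called; with a common median 3 were higher and 1 lower, and unscaled 3 and 0. With the floor at the 20th and at the 1st percentile, the log2 difference was 0.79 and 1.56 for GH9B11 and 0.62 and 2.57 for GH9B16. IYO was the 1 gene called among 10 nuclear developmental regulators and fell from 0.365 ± 0.0604 to 0.147 ± 0.117 (SD, n = 8 each; log2 -1.60, SE 0.32, adjusted p = 0.00147); with a common median 3 regulators were called lower and 0 higher, and unscaled 1 and 1. Of 6 organelle RNA and DNA factors 1 fell, AT5G55580 of the mTERF family (log2 -0.56, SE 0.18, adjusted p = 0.0227), a call lost unscaled (0.589), under cyclic loess (0.0996) and with consecutive numbers averaged (0.129), while unscaled 3 factors were called higher and 0 lower. Z-ISO, HEMA3, IYO, GH9B11 and GH9B16 kept their calls with consecutive numbers averaged, but Z-ISO (adjusted p = 0.0924), HEMA3 (0.0851) and IYO (0.107) lost them in the numbers 5 to 8 alone, and GH9B11 (0.0594) and GH9B16 (0.0842) in the numbers 1 to 4 alone. Of 7 plastid redox and chaperonin genes and of 6 photosystem and cytochrome subunits or assembly factors, 1 each rose, AT3G52960 and PSBW; unscaled 3 and 1 rose and 0 fell, and with a common median 2 and 0 rose and 0 and 3 fell, while under cyclic loess 1 and 1 rose and 1 and 0 fell. Camera called 0 of the 8 added lists after adjustment, and 1, the NDH list, had an unadjusted p under 0.05 (0.0304). Fry, which tests another question, gave adjusted p-values of 0.00422 for the cell wall enzymes and the developmental regulators and 0.00923 for the pigment list. It does not compare a list with the other probes, and 31.8% of all probes were called. Its small p-values, that of the NDH list included, therefore do not set a list apart.

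The 8 measured genes of the photosynthesis lists combined differed by scaling. They had a median log2 difference of -0.02 after quantile normalization, with 1 higher and 1 lower, 0.04 under cyclic loess, 0.02 unscaled and -0.71 with a common median, with 7 lower. In that order, limma's camera gave unadjusted p-values of 0.755, 0.869, 0.140 and 0.00224 for this list, 1 of 8 put together after the names were seen. The median of all probes was -0.05, -0.06, 0.41 and -0.18. Several of these genes are bright, such as PSBW (37.7 in WT), LHB1B2 (28.6) and PSAN (13.9). The unscaled log2 ratio was -0.00235 in the brightest of 10 classes and 0.713 in the class 5. A common median therefore puts bright probes as a group below 0, and its p-value does not set these genes apart from them.

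Genes on the chromosome of GUN1 could differ because of a chromosome segment from another line in the mutant stock. Of the named probes on chromosome 2, 37.9% were called, against 35.7% on the other 4, a difference of 2.2 percentage points (SE 4.80), and a permutation test over all 5 chromosomes gave p = 0.117. The shares were 41.1% on chromosome 3 and 40.0% on chromosome 4, both above that of chromosome 2. On chromosome 1 the share was 27.9% and on chromosome 5 36.6%, both below it. Of the 24 largest rises and falls, 8 are on chromosome 2, which has 124 of the 687 named probes, and 6 lie beyond AT2G31400, which has 64 of them; these genes raised the question and cannot test it. Of all named probes beyond AT2G31400, 35.9% were called, against 36.1% of the others, a difference of -0.178 percentage points (SE 6.30). That test showed no excess of calls beyond AT2G31400, and its SE leaves a short segment open. Probes on the other side of AT2G31400, HEMA3 (AT2G31250) among them, counted as others, so it did not test that side.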
